A study of Rattus norvegicus with 12 samples.

How the data were processed

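The study measured gene expression in NRK cells, an established line of normal rat kidney cells, by hybridising Cy3-labelled RNA to 1-colour oligonucleotide microarrays. The labels put 12 samples in 4 media with 3 biological replicates each: serum free medium, fetal bovine serum (FBS), serum from sham-treated animals (sham serum) and serum from animals with acute kidney injury (AKI serum). Per the labels' protocols, cells attached overnight in 10% FBS, and sham serum and AKI serum were then given at 10% for 48 hours. The subline of NRK, the species that gave the sera, the way the kidneys were injured and the time for which the other two media were used are not given in the sources used here.

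Per the file headers, each array was scanned and read with Agilent Feature Extraction 10.5.1.1, on array design 014879 with a grid placed on the rat genome build rn4 (release 3.4). The processed signal of each spot is an intensity from which the authors' scanner software subtracted the local background and removed spatial trends, per the file headers, and it was not normalised between arrays. The deposited mean signal and background signal of each spot are intensity values before that correction. The authors also deposited log2 values for the whole series in a single table. Compared with the scanner values of the same arrays, it held quantile normalised log2 processed signals that were not centred: every column had a median of 5.71, and its correlation with the array's own processed signals was 0.994 or higher.

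Each array held 45018 spots, of which 43379 were not controls and represented 41012 probes. Control spots and spots with an outlier flag were left out, and spots of 1 probe were averaged. No array had a saturated probe (0%). Normalised values were log2 of the processed signal minus the array's 75th percentile. A probe was kept where the scanner software called it well above background on all 3 arrays of at least 1 medium and at least 8 arrays gave a value. Probes were named through a reference table by accession (17368 probes), symbol (2672) or older symbol (621), 1001 probes kept the gene name of the scanner files, and 19350 had no gene name. Of several probes of a gene the one with the highest mean was used, which gave 25852 rows, 12883 of them with a gene symbol and 12412 of them probes without a name. A value was missing on at least 1 array for 227 rows.

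Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 12 arrays in 1 fit with medium as the only term, which left 8 residual degrees of freedom and 4.0 prior degrees of freedom. The 6 comparisons between media, an F test over all media and the rows that passed in the same direction in all 3 sera against serum free medium were the results. P-values were adjusted by the Benjamini-Hochberg method over all rows and the threshold was an adjusted p of 0.05. Fold changes are differences of mean normalised log2 values, errors of fold changes are standard errors from limma (SE), and errors of levels are standard deviations over 3 arrays (SD). Where no array of the dimmer medium had a probe well above background, the fold is a bound, written as "at least": the mean of the brighter medium is set against the mean of, per array, the higher of the dim probe's own value and the lowest value among the probes well above background on that array, and no fold is given where this is under 1. The bound holds for these background-subtracted values only. With the normexp correction described below, Cxcl3, Dysf, Mmp10, Scd and Lect2 differed by less than their bounds. For arrays, their number limits the precision. The labels call the replicates biological without saying how they were made, so p-values measure the spread between these samples.

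Gene lists were tested with camera from limma with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Camera used rows with a value on all 12 arrays, and a list was tested with 5 or more measured members. The 32 lists were NRF2 targets, antioxidant enzymes, superoxide and nitric oxide producing enzymes, kidney injury markers, inflammatory and NF-kB response, interferon response, mitosis, DNA replication, p53 targets, cholesterol synthesis, fatty acid synthesis, PPAR targets and fatty acid oxidation, immediate early genes, SRF and YAP targets with the actin cytoskeleton, extracellular matrix and TGF-beta response, unfolded protein response, ATF4 integrated stress response, heat shock response, hypoxia and glycolysis, mitochondrial respiration, complement and acute phase, metal handling, AhR targets, glucocorticoid responsive genes, circadian clock, epithelial markers, mesenchymal and fibroblast markers, proximal tubule markers, distal tubule and collecting duct markers, blood cell markers, endothelial markers and reference genes. Some genes are in more than 1 list. The lists, the design, the alternatives planned and the rule for named genes were fixed before the data were examined. That rule names, for AKI serum against sham serum, the 10 largest changes in each direction among rows that passed, had a gene symbol and had no overlap between the arrays of both media. For FBS, sham serum and AKI serum against serum free medium and sham serum against FBS it names 6 in each direction, and for AKI serum against FBS it gives counts and lists. Where fewer passed, all that passed are named. Up to 4 members with the smallest p are named in a list described, some genes that these rules give are left unnamed, and Hmox1, Nqo1, Havcr1 and Lcn2 are given for AKI serum against sham serum whatever their values. Genes that the same rule gives only with the replicate number in the fit were added after seeing the data and are named as such.

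The replicate number of the labels and the slide coincide: 3 slides held 4 arrays each, 1 of each medium, and were scanned on 2 days. Over the rows, arrays with the same number deviated from their group means together, with correlations of 0.40 to 0.76 (median 0.59) in all 18 pairs across media, against -0.50 to 0.04 (median -0.29) in the 36 pairs of different numbers. Deviations from a group mean sum to 0 within a medium, so the negative values largely follow from the positive ones and are no separate evidence. By the positive correlations the numbers pair the samples, through the slide or what was shared with it. The fit with the replicate number as a block is given beside a result where it changed a call or moved a count by over 1.5 times. Of the list members whose call changed with the block, only some are named. On a slide the position was the same for a medium on all 3 slides.

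The steps were tested on simulated data with the rows and spread of AKI serum against sham serum (25625 rows, 67, 67 and 66 of them changed 2-fold, 4-fold and 8-fold). The fit without the block was given data with its own residual spread and no slide differences. There limma called 13.4%, 65.7% and 98.5% of the rows changed 2-fold, 4-fold and 8-fold, with 6 false calls. The fit with the block was given separate data, with the residual spread of that fit and the slide differences added. There it called 46.3%, 92.5% and 98.5%, with 9 false calls. The fits were thus not compared on the same data. The fit without the block was not tried on data with slide differences, so its values may not hold for these arrays. A list of 27 rows shifted by 0.6 was called by camera (adjusted p = 1.0e-10), and 0 of 30 unchanged lists were. Rows were drawn independently of each other, so this is no test of false list calls among correlated genes.

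The alternatives were quantile normalisation, median centring, normexp background correction with an offset of 50 on the mean and background signals, normexp with quantile normalisation, the deposited log2 table, no filter on dim probes, a filter for signal on all 12 arrays, every probe as its own row, the mean of the probes of a gene, a size threshold of 1 on the log2 scale, array weights, eBayes with trend and robust, the replicate block, a fit on the 2 groups compared, and each array left out in turn. Random lists (10000 draws matched on mean signal), 10 splits of each pair of media, 100 regroupings of the 12 arrays and 50 simulated draws for the shared serum free arrays were used for checks. Input was read with the R packages data.table (version 1.17.8) and jsonlite (version 2.0.0), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Positions of probes are those of the scanner files on rn4; no genome of that build was used here, so the part of the transcript that a probe covers was not analysed here.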

Results

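The arrays compared NRK cells, a line from normal rat kidney, kept in serum free medium, FBS, sham serum or AKI serum, with 3 arrays per medium. The series title names proteins that acutely injured kidneys release into serum and oxidative stress, so AKI serum against sham serum was the central comparison. On the arrays, 57.6% (serum free replicate 3) to 82.7% (AKI serum replicate 1) of the probes were well above background. On every slide this share was lowest in serum free medium (72.3%, 67.5% and 57.6% on slides 1, 2 and 3). It was highest in AKI serum (82.7%, 72.4% and 76.6%), above sham serum (77.8%, 69.3% and 71.0%). Each medium held 1 position on the slides, so medium and position cannot be told apart here. The 75th percentile of the processed signal lay between 597 (sham serum replicate 2) and 845 (FBS replicate 1). Serum free replicate 3 also had the most spots with an outlier flag, 301 against 45 to 157 on the other arrays. Normalised log2 values correlated at 0.971 to 0.988 over the rows within a medium and at 0.958 to 0.995 between media.

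Chymosin (Cym), a secreted aspartic protease, and glutathione S-transferase alpha 2 (Gsta2), an enzyme that conjugates glutathione to electrophiles, rose in AKI serum against sham serum. Cym was 10.1-fold higher (log2 3.34 ± 0.26, SE, n = 3 arrays per medium, limma adjusted p = 5.7e-04), with differences of 3.96, 3.24 and 2.83 on slides 1, 2 and 3. Its normalised log2 level was 0.98 ± 0.45 (SD, n = 3) in AKI serum, against -2.36 ± 0.16 in sham serum, -2.54 ± 0.16 in FBS and -2.73 ± 0.31 in serum free medium. Gsta2 was 7.96-fold higher (log2 2.99 ± 0.27, SE, limma adjusted p = 0.0016), with differences of 3.52, 2.74 and 2.71 on the slides, and its other probe differed by 4.44. The level of Gsta2 was -1.81 ± 0.42 (SD, n = 3) in AKI serum, -4.80 ± 0.26 in sham serum, -4.68 ± 0.11 in FBS and -5.55 ± 0.38 in serum free medium, where 2 of 3 arrays had it well above background. The probe of Cym lies on chromosome 2 of rn4 from 202683462 to 202684258, and that of Gsta2 on chromosome 8 from 83302934 to 83302993.

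These 2 rows, both higher in AKI serum, were all that passed in limma among the 25852, with 293 rows at an unadjusted p under 0.05. Both passed without each of the 6 arrays in turn, and a limma fit on the 6 arrays alone called 0 rows (427 at an unadjusted p under 0.05). With the replicate block 13 rows passed in limma, all higher in AKI serum, and Cym (adjusted p = 8.4e-04) and Gsta2 (adjusted p = 0.0020) were among them. With the block, quantile normalisation gave 3 calls, all higher, and normexp gave 29, of which 28 were higher and 1 lower. Leaving out replicate 1, 2 or 3 from the fit with the block left 2, 0 and 0 rows (1081 and 1227 at an unadjusted p under 0.05 without replicates 2 and 3).

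The other 8 named genes passed only with the block and were added after seeing the data; with quantile normalisation the block called 3 rows instead of 13. Akr1b8, an aldo-keto reductase, was 5.31-fold higher in AKI serum (log2 2.41 ± 0.29, SE with the block, limma adjusted p = 0.036 with the block, 0.67 without it). Akr7a3 was 4.76-fold higher and Akr1c15 6.11-fold, both aldo-keto reductases and both at a limma adjusted p of 0.036 with the block, although the arrays of Akr1c15 overlapped. Entpd5, a nucleoside diphosphatase of the endoplasmic reticulum, was 2.85-fold higher (log2 1.51 ± 0.16, limma adjusted p = 0.028 with the block). The ABC transporter Abcc4 was 2.44-fold higher with overlapping arrays (limma adjusted p = 0.042 with the block). Adh7, an alcohol dehydrogenase, was at least 2.17-fold higher, Spmip7 at least 2.09-fold and the transporter Abca17 at least 1.19-fold (limma adjusted p = 0.036, 0.038 and 0.042 with the block). The remaining 3 were probes without a gene name.

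Hmox1, the inducible heme oxygenase, and Nqo1, a quinone reductase, were higher in AKI serum without passing the test over all rows. Hmox1 differed by 2.54 ± 0.75 on the log2 scale (SE, limma adjusted p = 1), with 3.22, 2.60 and 1.80 on the slides. Its level was 3.63 ± 0.82 (SD, n = 3) against 1.09 ± 0.97 in sham serum, 0.75 ± 0.74 in FBS and 1.78 ± 1.63 in serum free medium. Nqo1 differed by 1.18 ± 0.28 (SE, limma adjusted p = 1), with 1.09, 1.91 and 0.55 on the slides. Its levels were 3.32 ± 0.49 against 2.14 ± 0.29, 1.99 ± 0.29 and 1.93 ± 0.19 in the same order. The tubular injury markers Havcr1 (kidney injury molecule 1) and Lcn2 (lipocalin 2) differed by -0.04 ± 0.23 and -0.50 ± 0.45 (limma adjusted p = 1 for both). Havcr1 had mean levels of -4.41 in AKI serum, -4.37 in sham serum, -4.52 in FBS and -4.63 in serum free medium. The mean levels of Lcn2 were -3.45, -2.95, -3.42 and -3.29 in the same order. The probes of Hmox1 and Nqo1 lie on chromosome 19 from 13969336 to 13969395 and from 37256979 to 37257038.

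**Figure D1:**
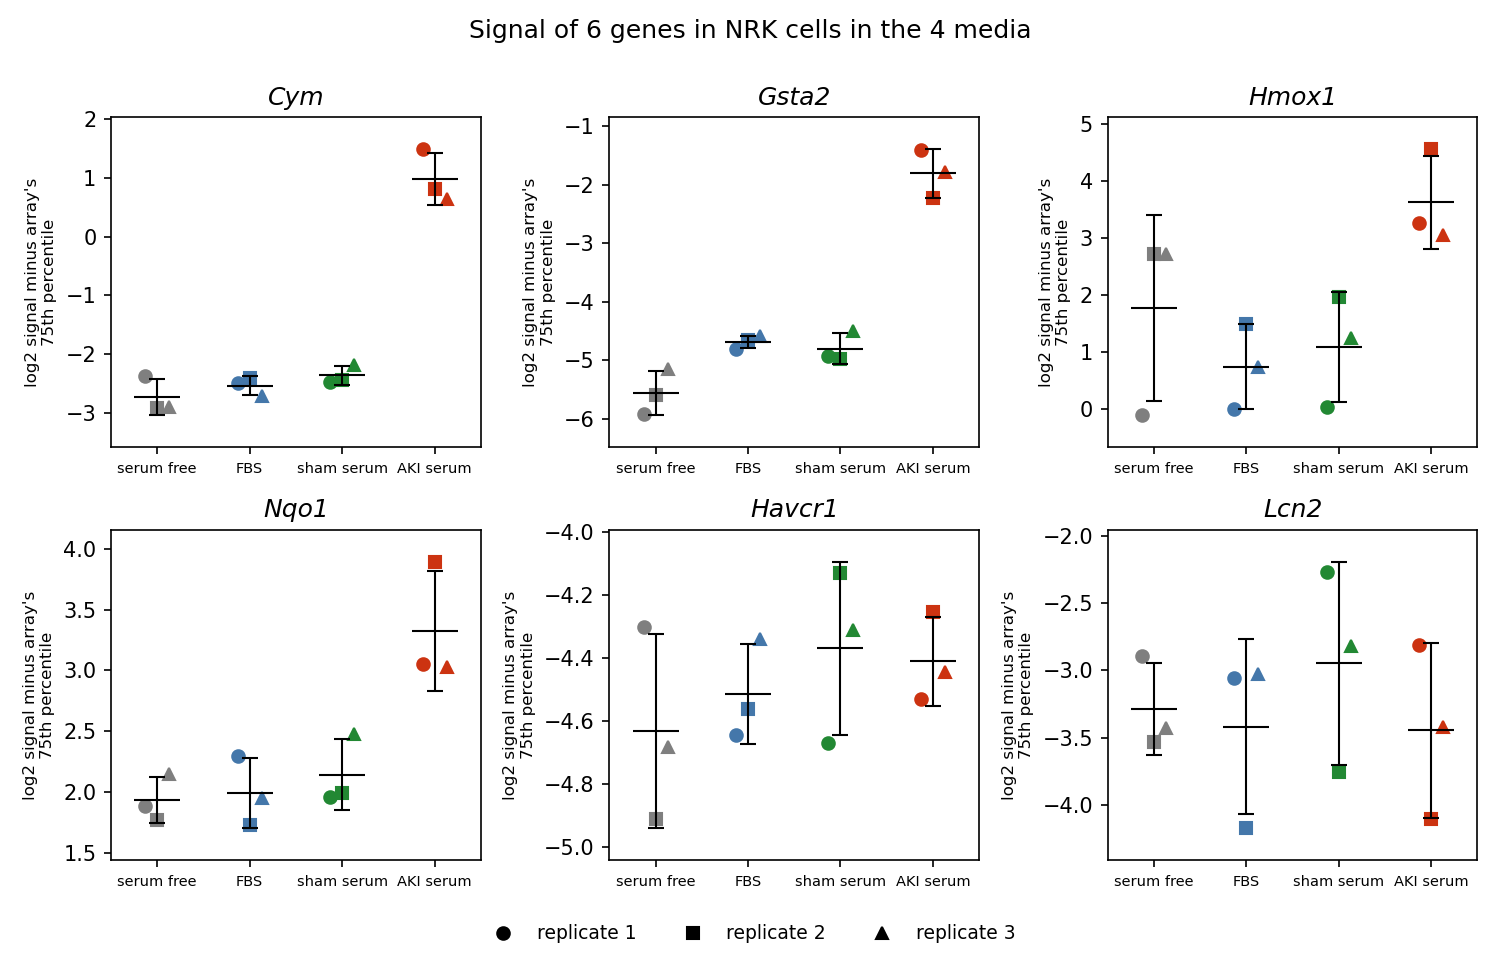
Normalised log2 signal (array's 75th percentile subtracted) of Cym, Gsta2, Hmox1, Nqo1, Havcr1 and Lcn2 by medium, with 1 point per array, the symbol giving the replicate, and bars for the mean ± SD of 3 arrays. Cym stood at 0.98 ± 0.45 in AKI serum and at -2.36 ± 0.16 in sham serum, while Havcr1 had means between -4.63 and -4.37 in all media.

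NRF2 targets, the antioxidant and detoxification genes that this transcription factor induces, rose together in AKI serum against sham serum. The median of the 27 measured members was 0.64 and the mean 0.91 (camera adjusted p = 3.8e-29, or adjusted p = 9.3e-04 with an estimated correlation), and the median was 0.59, 0.70 and 0.51 on slides 1, 2 and 3. No member passed over all rows in limma (0 of 27), and 6 rose when adjusted over the list alone: Hmox1, Gclm, Akr1b8, Gsta3, Srxn1 and Nqo1. Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, differed by 2.51 ± 0.46 with 1 of 3 sham serum arrays well above background, and Srxn1, sulfiredoxin, by 1.40 ± 0.27 with 2 of 3 (limma adjusted p = 0.0037 and 0.0040 over the list alone). With the block 1 member passed over all rows and 19 when adjusted over the list alone, and camera gave an adjusted p of 1.8e-25 (adjusted p = 0.070 with an estimated correlation and the block).

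**Figure D2:**
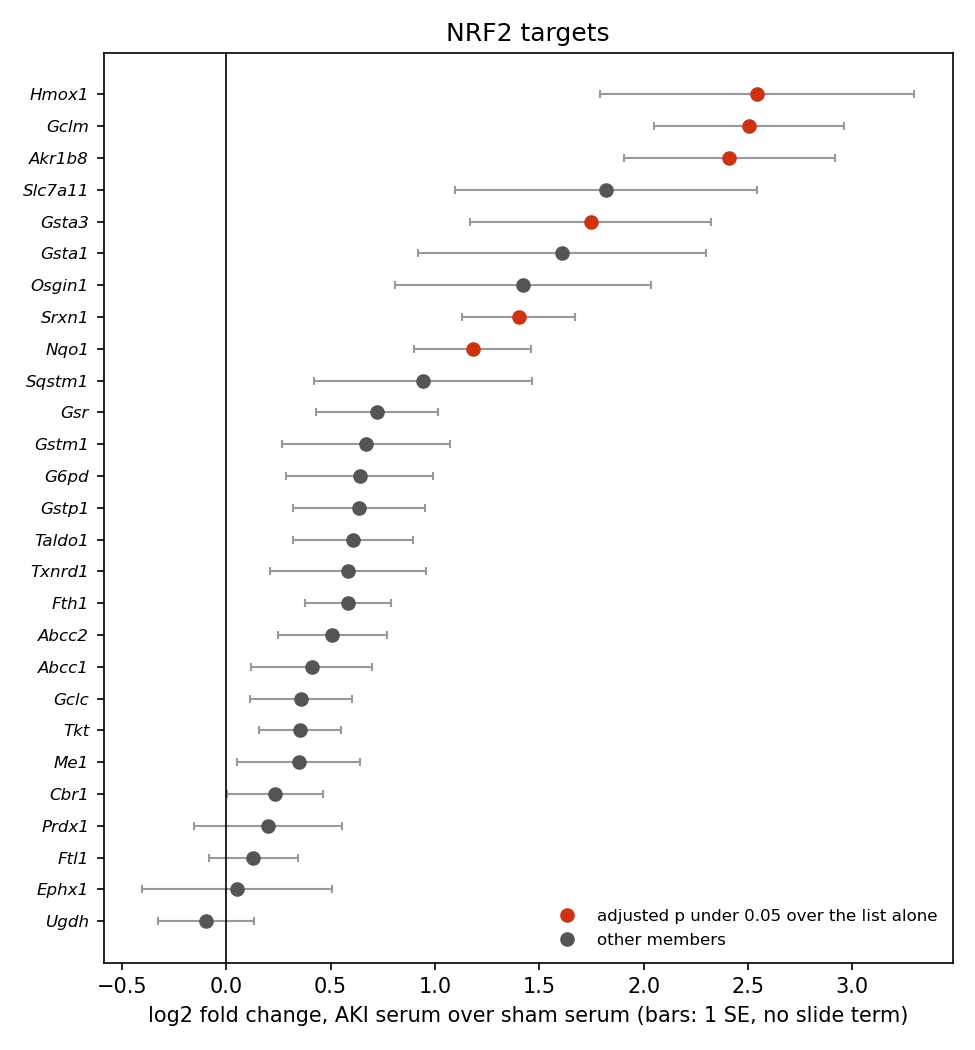
Log2 fold change of AKI serum over sham serum for the 27 measured NRF2 targets, with bars of 1 SE and red for the 6 members with an adjusted p under 0.05 when adjusted over the list alone. Most members lie above 0 and the median is 0.64.

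Cell cycle genes fell as lists in AKI serum against sham serum, by small amounts. The 23 mitosis genes had a median of -0.28 (camera adjusted p = 2.5e-05, or adjusted p = 0.61 with an estimated correlation) and medians of -0.22, -0.32 and -0.30 on the slides. DNA replication genes, 26 of them, had a median of -0.25 (camera adjusted p = 9.1e-05, or adjusted p = 0.61 with an estimated correlation), and -0.38, -0.29 and -0.15 on the slides. No member of either list passed in limma (0, also when adjusted over the list alone). Cdca8 and Aurkb, both of the chromosomal passenger complex, differed by -0.45 ± 0.30 and -0.34 ± 0.25, and the helicase subunit Mcm7 by -0.84 ± 0.51.

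Further lists passed camera upward with the preset correlation alone, and no member of them passed in limma over all rows (0). ATF4 integrated stress response had a median of 0.20 (camera adjusted p = 0.0012, or adjusted p = 0.45 with an estimated correlation) but -0.21 on slide 2, against 0.68 and 0.14 on slides 1 and 3. Among AhR targets Nqo1 alone rose when adjusted over the list alone without the block. With the block Cyp1a1 rose as well (log2 1.11, limma adjusted p = 0.029 over the list alone). The other upward medians were 0.33 for AhR targets, 0.07 for antioxidant enzymes, 0.21 for PPAR targets and fatty acid oxidation and 0.13 for metal handling. Their camera adjusted p was 0.0033, 0.010, 0.015 and 0.020 (adjusted p = 0.25, 0.61, 0.61 and 0.24 with an estimated correlation). Interferon response (0.16) and superoxide and nitric oxide producing enzymes (0.19) both had a camera adjusted p of 0.035 (adjusted p = 0.61 and 0.39 with an estimated correlation). SRF and YAP targets passed downward, with a median of -0.13 (camera adjusted p = 0.0496, or adjusted p = 0.83 with an estimated correlation). Catalase (Cat), which breaks down hydrogen peroxide, was 2.14-fold higher (limma adjusted p = 1), and the ferritin heavy chain Fth1 differed by 0.58 ± 0.20. In the fit with the block Cat, Gpx2 and Gss rose when adjusted over antioxidant enzymes alone (limma adjusted p = 0.0028, 0.015 and 0.045). Slc40a1 and Fth1 did so over metal handling and Aox1 over superoxide and nitric oxide producing enzymes (limma adjusted p = 0.0079, 0.042 and 0.038). With the block, leaving out replicate 1 lost the calls of antioxidant enzymes, superoxide and nitric oxide producing enzymes, interferon response and ATF4 integrated stress response (camera adjusted p = 0.051, 0.054, 0.075 and 0.55), and leaving out replicate 2 lost all of these lists but ATF4 integrated stress response (camera adjusted p = 0.10 to 0.33). Without replicate 3 SRF and YAP targets and metal handling were lost (camera adjusted p = 0.053 for both).

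The other 21 lists did not pass in this comparison. Kidney injury markers had a median of -0.04, a mean of 0.02 and a downward test (camera adjusted p = 0.87). Inflammatory and NF-kB response (0.04), hypoxia and glycolysis (0.07), p53 targets (0.11), circadian clock (0.06), epithelial markers (0.05), proximal tubule markers (0.05), blood cell markers (0.12) and endothelial markers (0.13) had medians above 0, with a camera adjusted p of 0.13 or more. Cholesterol synthesis (-0.07), unfolded protein response (-0.04), extracellular matrix and TGF-beta response (-0.04), mitochondrial respiration (-0.08), complement and acute phase (-0.04), glucocorticoid responsive genes (-0.12), mesenchymal and fibroblast markers (-0.16), distal tubule and collecting duct markers (-0.02) and reference genes (-0.08) had medians below 0, likewise with 0.13 or more. Median and test differed in sign for fatty acid synthesis (median -0.02, mean 0.10, upward test, camera adjusted p = 0.74) and immediate early genes (median -0.03, mean 0.08, upward test, camera adjusted p = 0.90). Heat shock response had a median of -0.02, a mean of 0.01 and a downward test (camera adjusted p = 0.99). Without replicate 1, in the fit with the block, cholesterol synthesis had a median of 0.12 and an upward test (camera adjusted p = 0.025), as did hypoxia and glycolysis with 0.14 (camera adjusted p = 0.020).

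FBS against serum free medium asked what ordinary culture serum changes. Arrdc3, an arrestin-domain protein, rose 4.45-fold in FBS (log2 2.15 ± 0.28, SE, n = 3 arrays per medium, limma adjusted p = 0.030), the chemokine Cxcl3 at least 2.13-fold (log2 2.36 ± 0.30, limma adjusted p = 0.030) and the zinc finger gene Zfp395 2.65-fold (log2 1.40 ± 0.20, limma adjusted p = 0.046). Slc2a6, a hexose transporter, fell 5.82-fold (log2 -2.54 ± 0.37, limma adjusted p = 0.046; probe on chromosome 3 from 5918004 to 5918063). After normexp Cxcl3 differed by 0.10 (limma adjusted p = 0.90), and Zfp395 by 0.85 and Slc2a6 by -2.17 (limma adjusted p = 0.078 and 0.056). All 4 moved the same way on the 3 slides, Slc2a6 by -2.12, -3.67 and -1.83. The 6 other rows that passed, all lower in FBS, were probes without a gene name.

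Of the 25852 rows, 10 passed in limma (3 higher and 7 lower in FBS), and 2528 had an unadjusted p under 0.05. In the fit with the replicate block 1330 rows passed, 717 higher and 613 lower. Median centring, quantile normalisation or the deposited log2 table gave 50% higher rows among those called and normexp 14.3%, against 30% here. The count was 332 without serum free replicate 1, 3 without serum free replicate 2, and 0 (2594 at an unadjusted p under 0.05 in limma), 1 and 2 without FBS replicates 1, 2 and 3. The calls of the 4 named genes were lost without any 1 FBS array or serum free replicate 2 (limma adjusted p = 0.052 to 0.34). With the block it was 838 without replicate 1, and 0 without replicate 2 or 3 (4270 and 4222 at an unadjusted p under 0.05 in limma).

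Cholesterol synthesis genes, from the mevalonate pathway to the last steps of sterol synthesis, fell as a list in FBS. The 26 members had a median of -1.16 (camera adjusted p = 5.7e-23, or adjusted p = 0.11 with an estimated correlation), with -0.67, -1.76 and -1.09 on slides 1, 2 and 3. No member passed over all rows in limma (0), and 21 fell when adjusted over the list alone, among them Cyp51 (log2 -1.51 ± 0.25), squalene epoxidase Sqle (-1.17 ± 0.24), Acat2 (-1.95 ± 0.41) and Pmvk (-1.43 ± 0.30). With the block 18 members fell over all rows and 22 when adjusted over the list alone. Fatty acid synthesis, 17 members, had a median of -0.59 (camera adjusted p = 2.3e-07, or adjusted p = 0.11 with an estimated correlation), and 6 fell when adjusted over the list alone, including fatty acid synthase Fasn (-1.28 ± 0.33) and Elovl6 (-1.14 ± 0.30). With the block 7 of these fell over all rows.

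Immediate early genes had a median of -0.61 in FBS (camera adjusted p = 2.6e-04, or adjusted p = 0.30 with an estimated correlation), and the phosphatase Dusp5 (-1.71 ± 0.33) and Ier3 (-1.16 ± 0.27) fell when adjusted over the list alone. Heat shock response had a median of -0.21 (camera adjusted p = 0.0083, or adjusted p = 0.72 with an estimated correlation), and the co-chaperone Dnajb1 (-1.65 ± 0.33) and the chaperone Hspa1b (-1.18 ± 0.32) fell when adjusted over the list alone. Over all rows Dusp5, Ier3, Dnajb1 and Hspa1b passed with the block (limma adjusted p = 0.022, 0.022, 0.028 and 0.043). The immediate early gene Ier5 and the heat shock gene Cryab also fell there (limma adjusted p = 0.022 and 0.040). Against the direction of its list, the immediate early gene Fosl2 rose (log2 1.17, limma adjusted p = 0.027 with the block). With the block immediate early genes lost their call without replicate 2 (camera adjusted p = 0.24) and heat shock response without replicate 3 (camera adjusted p = 0.10). The p53 targets passed only with the block (median -0.27; camera adjusted p = 0.042, 0.090 without it, or adjusted p = 0.51 with an estimated correlation and the block). Among genes that the rule names only with the block, added after seeing the data, were the imprinted transcript H19, 4.68-fold higher (limma adjusted p = 0.010), and the lower Scd (log2 -3.42, or adjusted p = 0.024), Sult1c2a (-2.97; 0.022), Tm7sf2 (-2.76; 0.016) and Sult1c2 (-2.50; 0.019).

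Sham serum against serum free medium gave the response to serum of animals without kidney injury. Srpx2, a secreted sushi-repeat protein, rose 29.4-fold (log2 4.88 ± 0.55, SE, n = 3 arrays per medium, limma adjusted p = 0.0057; 2 of 3 serum free arrays well above background; probe on chromosome X from 121468224 to 121468283). Angptl4, a secreted inhibitor of lipoprotein lipase, rose 7.74-fold (limma adjusted p = 0.0057), and the membrane repair protein dysferlin (Dysf) at least 3.76-fold (limma adjusted p = 0.0057). The serine protease Prss22 rose 7.89-fold (limma adjusted p = 0.020), the nuclease Dnase1l3 14.7-fold (limma adjusted p = 0.048) and the matrix metalloprotease Mmp10 at least 2.93-fold (limma adjusted p = 0.019). Igfbp3, which binds insulin-like growth factors in the medium, fell 35.3-fold (log2 -5.14 ± 0.80, limma adjusted p = 0.019; other probe -4.93), and the stearoyl-CoA desaturase Scd at least 12.6-fold (limma adjusted p = 0.015). The sulfotransferase Sult1c2a fell 14.5-fold (limma adjusted p = 0.011), the sterol reductase Tm7sf2 14.4-fold, the ubiquitin ligase of the LDL receptor Mylip 13.7-fold (both with limma adjusted p = 0.019; the other probe of Mylip differed by -0.73) and Degs1l2 at least 7.91-fold (limma adjusted p = 0.014).

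In limma 222 rows passed, 73 higher and 149 lower in sham serum (32.9% higher; 22% after normexp, where 141 passed), and 4217 rows had an unadjusted p under 0.05. After normexp Mmp10 differed by 0.52, Dysf by 0.46 and Scd by -1.36, and none of them passed (limma adjusted p = 0.46, 0.36 and 0.075). Each of these differences was smaller than the bound given above. With the replicate block 4433 passed, 2517 higher and 1916 lower. The rule then also names Sult1a1 (log2 4.13, limma adjusted p = 0.0020) and the aquaglyceroporin Aqp9 (log2 3.15, limma adjusted p = 0.0034). The count was 564 without serum free replicate 1 and 36 without serum free replicate 3, and 68, 28 and 14 without sham serum replicates 1, 2 and 3. With the block the count was 1662, 2333 and 32 without replicates 1, 2 and 3. A limma fit on these 6 arrays alone called 0 (2895 at an unadjusted p under 0.05). Srpx2, Angptl4 and Dysf passed without each single array in turn, and the other 9 named genes lost their calls without sham serum replicate 2 (limma adjusted p = 0.051 to 0.13), 7 of them also without sham serum replicate 3 and 6 without serum free replicate 3, and Dnase1l3 also without replicate 1 of either medium (limma adjusted p = 0.076 and 0.099).

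Cholesterol synthesis, fatty acid synthesis and immediate early genes passed downward as lists in sham serum with the preset correlation, and not with an estimated one. Cholesterol synthesis had a median of -1.19 (camera adjusted p = 6.0e-16, or adjusted p = 0.18 with an estimated correlation), with -0.71, -1.64 and -0.90 on the slides. There 5 of 26 members fell over all rows and 18 when adjusted over the list alone, among them Tm7sf2, Cyp51 (-1.41 ± 0.25) and Mvd (-1.87 ± 0.36). Fatty acid synthesis had a median of -1.05 (camera adjusted p = 3.2e-08, or adjusted p = 0.14 with an estimated correlation). In this list 5 of 17 members fell over all rows and 8 when adjusted over the list alone, with Scd2 at -1.90 ± 0.27, Elovl6 at -1.71 ± 0.30 and Fasn at -1.84 ± 0.33. Immediate early genes had a median of -0.82 (camera adjusted p = 6.1e-08, or adjusted p = 0.14 with an estimated correlation), with no member past the test over all rows (0 in limma) and 14 lower when adjusted over the list alone, such as Spry4 (-1.25 ± 0.26) and Ier2 (-2.22 ± 0.51). With the block 17, 10 and 11 members of these lists fell over all rows, and 1 immediate early gene rose.

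Lists that rose in sham serum passed with the preset correlation alone. Hypoxia and glycolysis had a median of 0.34 (camera adjusted p = 0.0091, or adjusted p = 0.62 with an estimated correlation) with no member past the test over all rows (0 in limma). With the block the hexokinase Hk2, Ldha and Pgk1 rose over all rows (limma adjusted p = 0.0074, 0.029 and 0.035), as did 6 PPAR targets and 3 distal tubule and collecting duct markers. PPAR targets and fatty acid oxidation had a median of 0.35 and Angptl4 as the 1 member that rose, and distal tubule and collecting duct markers a median of 0.48, or -0.01 after normexp (camera adjusted p = 0.027 for both, or adjusted p = 0.85 and 0.35 with an estimated correlation). With the block hypoxia and glycolysis lost its call without replicate 1 (camera adjusted p = 0.16), distal tubule and collecting duct markers without replicate 2 or 3 (camera adjusted p = 0.051 and 0.21) and PPAR targets without replicate 3 (camera adjusted p = 0.076). Among lists that did not pass, the selenoproteins Selenow (log2 1.86 ± 0.21, limma adjusted p = 0.0057) and Gpx1 (1.85 ± 0.27, limma adjusted p = 0.015) rose, as did the proximal tubule enzyme Ggt1 (2.66 ± 0.46, limma adjusted p = 0.029), Usp18 (1.24 ± 0.22, limma adjusted p = 0.032) and the receptor kinase Axl (1.25 ± 0.22, limma adjusted p = 0.029).

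AKI serum against serum free medium moved the most rows. Srpx2 rose 22.6-fold (log2 4.50 ± 0.55, SE, n = 3 arrays per medium, limma adjusted p = 0.0052), Akr1b8 16.6-fold (4.06 ± 0.51, limma adjusted p = 0.0053), Gsta2 13.4-fold and Cym 13.1-fold (limma adjusted p = 1.2e-04 for both). Ptgr1, a reductase of prostaglandins and reactive aldehydes, rose 15.2-fold and Trim54, a muscle ring finger protein, 10.8-fold (limma adjusted p = 0.0065 for both), with Trim54 well above background on 1 serum free array. Igfbp3 fell 58.2-fold (log2 -5.86 ± 0.80, limma adjusted p = 0.0071), by -6.36, -3.81 and -7.42 on the slides. Tm7sf2 fell 16.7-fold, Mylip 13.3-fold, Sult1c2a 12.7-fold, Scd 12.2-fold and Degs1l2 11.3-fold (limma adjusted p = 0.0087, 0.011, 0.0075, 0.013 and 0.0077), with Scd and Degs1l2 well above background on 2 of 3 AKI serum arrays. The other probe of Mylip differed by -1.61, that of Igfbp3 by -5.40 and that of Gsta2 by 4.96. The probe of Akr1b8 lies on chromosome 4 from 61724364 to 61725032 and that of Ptgr1 on chromosome 5 from 77010948 to 77011007. The level of Akr1b8 was 2.42 ± 0.81 (SD, n = 3) in serum free medium, 2.25 ± 0.13 in FBS, 4.07 ± 0.68 in sham serum and 6.47 ± 0.95 in AKI serum.

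In limma 777 rows passed, 406 higher and 371 lower in AKI serum (52.3% higher), 368 and 352 of them by at least 2-fold, and 4991 had an unadjusted p under 0.05. Normexp called 455, 134 higher and 321 lower (29.5% higher). With the replicate block 6206 passed, 3623 higher and 2583 lower. The rule then also names Mgp, matrix Gla protein, at 11.3-fold lower (limma adjusted p = 0.0018). The count was 226 without serum free replicate 3, and 170, 282 and 133 without AKI serum replicates 1, 2 and 3. With the block the count was 2313, 3459 and 945 without replicates 1, 2 and 3. Scd lost its call without AKI serum replicates 1 and 2 (limma adjusted p = 0.057 and 0.050).

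NRF2 targets rose as a list in AKI serum against serum free medium, with a median of 0.88 (camera adjusted p = 2.3e-08, or adjusted p = 0.069 with an estimated correlation) and 0.77, 0.84 and 0.88 on the slides. Of 27 members 8 rose over all rows and 11 when adjusted over the list alone, with Akr1b8, Gclm at least 2.64-fold (log2 2.97 ± 0.46), Srxn1 (1.62 ± 0.24) and the transporter Abcc2 (1.66 ± 0.26) the clearest. With the block 16 and 20 members rose. Cholesterol synthesis had a median of -1.24 (camera adjusted p = 8.6e-15, or adjusted p = 0.16 with an estimated correlation), with -1.24, -1.63 and -0.88 on the slides. Of 26 members 14 fell over all rows, such as Mvd (-2.18 ± 0.36) and Cyp51 (-1.40 ± 0.25), while 22 fell and 1 rose when adjusted over the list alone. Fatty acid synthesis had a median of -0.95 (camera adjusted p = 1.2e-06, or adjusted p = 0.14 with an estimated correlation), with 6 of 17 members lower and 9 when adjusted over the list alone. Immediate early genes had a median of -0.78 (camera adjusted p = 1.3e-06, or adjusted p = 0.16 with an estimated correlation), and Egr2 (-2.55 ± 0.46), Spry4 (-1.40 ± 0.26), Srf (-1.56 ± 0.32) and Jun (-1.80 ± 0.42) were among 5 of 26 members that fell, 10 when adjusted over the list alone. With the block 20 cholesterol synthesis genes fell and 2 rose over all rows, 10 fatty acid synthesis genes fell, and 11 immediate early genes fell and 2 rose.

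PPAR targets and fatty acid oxidation (median 0.56) and hypoxia and glycolysis (median 0.48) also passed upward in AKI serum against serum free medium (camera adjusted p = 9.1e-04 and 0.0012, or adjusted p = 0.47 and 0.37 with an estimated correlation). Angptl4 (log2 3.34 ± 0.34, limma adjusted p = 0.0024) was the 1 PPAR target that rose, and no hypoxia gene passed over all rows (0 in limma). With the block 9 PPAR targets rose and 1 fell over all rows, and 8 hypoxia and glycolysis genes rose. The NRF2 target Slc7a11, a cystine transporter, rose at least 3.84-fold (limma adjusted p = 0.043). In lists that did not pass, Ggt1 rose by 3.06 ± 0.46 on the log2 scale (limma adjusted p = 0.0094), the monoamine oxidase Maoa by 0.87 ± 0.20 (limma adjusted p = 0.043) and the ferritin heavy chain Fth1 by 0.92 ± 0.20 (limma adjusted p = 0.036), and the proapoptotic Bbc3 fell by 1.37 (SE 0.24, limma adjusted p = 0.015).

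Sham serum against FBS set serum of uninjured animals against the usual culture serum. Srpx2 rose 25-fold in sham serum (log2 4.65 ± 0.55, SE, n = 3 arrays per medium, limma adjusted p = 0.020), Angptl4 11.5-fold (3.52 ± 0.34, limma adjusted p = 0.0069), and Lect2, a secreted chemotactic factor, at least 2.55-fold (2.44 ± 0.29, limma adjusted p = 0.020). After normexp Lect2 differed by 0.31 (limma adjusted p = 1.0), and after quantile normalisation Srpx2 and Lect2 had a limma adjusted p of 0.16 and 0.051. Srpx2, Angptl4 and Lect2 were the 3 rows that passed, all higher, with 1551 at an unadjusted p under 0.05. Once the replicate block was in the fit, 629 rows passed, 350 higher and 279 lower. The count was 0, 0 and 1 without FBS replicates 1, 2 and 3 and 0 without sham serum replicates 2 or 3 (1289, 1710, 1325 and 1521 at an unadjusted p under 0.05 in limma where it was 0). With the block the count was 9, 122 and 0 without replicates 1, 2 and 3 (2617 at an unadjusted p under 0.05 in limma without the third).

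Genes named only with the block, added after seeing the data, included Il1rl1, the interleukin 33 receptor, 56.4-fold higher in sham serum (limma adjusted p = 0.014), Nppb, the natriuretic peptide B gene, 15.8-fold (limma adjusted p = 0.0084), and Dnase1l3 (log2 4.02, limma adjusted p = 0.0080). Igfbp3 was 38.8-fold lower (limma adjusted p = 0.0060), Mgp 9.80-fold (limma adjusted p = 0.010), the complement gene Cfb 9.65-fold (limma adjusted p = 0.011) and the complement inhibitor Serping1 6.47-fold (limma adjusted p = 0.020), all with the block.

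Glycolysis and hypoxia genes led the 16 lists that passed between sham serum and FBS. Hypoxia and glycolysis had a median of 0.56 (camera adjusted p = 5.9e-08, or adjusted p = 0.28 with an estimated correlation) and 0.71, 0.38 and 0.74 on the slides. In limma 0 of 25 members passed over all rows, and 10 rose and 1 fell when adjusted over the list alone, with Tpi1 (log2 1.97 ± 0.39), Pdk1 (2.22 ± 0.46), Ankrd37 (1.55 ± 0.34) and Bnip3 (1.76 ± 0.41) the clearest. With the block 10 members rose over all rows, as did 3 PPAR targets, 3 SRF and YAP targets, 2 kidney injury markers, 1 NRF2 target and 1 distal tubule and collecting duct marker. PPAR targets and fatty acid oxidation (0.40), SRF and YAP targets (0.37), NRF2 targets (0.28), kidney injury markers (0.34), distal tubule and collecting duct markers (0.20) and mitochondrial respiration (0.24) also had higher medians in sham serum (camera adjusted p = 0.0033, 0.0093, 0.015, 0.024, 0.035 and 0.038, or adjusted p = 0.49, 0.63, 0.39, 0.28, 0.39 and 0.65 with an estimated correlation). Immediate early genes (-0.26) and fatty acid synthesis (-0.16) had lower ones (camera adjusted p = 0.0050 and 0.022, or adjusted p = 0.39 and 0.42 with an estimated correlation).

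The remaining 7 lists lost their call with the block. AhR targets had a median of -0.41 (camera adjusted p = 0.020, 0.058 with the block, or adjusted p = 0.39 with an estimated correlation), and Cyp1a1, the classical target of this receptor, fell by 2.37 (SE 0.42, limma adjusted p = 9.6e-04 over the list alone, and 0.011 over all rows with the block). Glucocorticoid responsive genes (0.20) and unfolded protein response (0.17) had a camera adjusted p of 0.035 (0.17 and 0.081 with the block, or adjusted p = 0.49 and 0.65 with an estimated correlation). Antioxidant enzymes (0.14), ATF4 integrated stress response (0.27), inflammatory and NF-kB response (0.16) and reference genes (0.10) had a camera adjusted p of 0.038 (0.081, 0.12, 0.12 and 0.055 with the block, or adjusted p = 0.63, 0.63, 0.41 and 0.63 with an estimated correlation). Of the 16 lists, hypoxia and glycolysis and PPAR targets alone kept their calls with the block without each replicate in turn. The other 14 lost theirs without at least 1 (camera adjusted p = 0.057 to 0.70), as NRF2 targets did without replicate 3 (camera adjusted p = 0.44).

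NRF2 targets also stood higher in AKI serum than in FBS. Their median was 0.96 (camera adjusted p = 2.6e-17, or adjusted p = 0.0059 with an estimated correlation, 0.25 with the block and an estimated correlation), with 0.83, 0.91 and 1.06 on the slides. Akr1b8 (log2 4.22 ± 0.51, SE, limma adjusted p = 0.0088) and Srxn1 (1.72 ± 0.24, limma adjusted p = 0.023) rose over all rows, and 17 of 27 members when adjusted over the list alone. With the block 17 of them rose over all rows. Hypoxia and glycolysis had a median of 0.62 (camera adjusted p = 2.0e-08, or adjusted p = 0.22 with an estimated correlation) with 12 of 25 members higher when adjusted over the list alone, and 13 over all rows with the block. PPAR targets (0.61), ATF4 integrated stress response (0.52) and antioxidant enzymes (0.37) had higher medians and immediate early genes a lower one (-0.14), with a camera adjusted p of 2.4e-05, 2.1e-04, 6.5e-04 and 0.028 (adjusted p = 0.43, 0.43, 0.44 and 0.49 with an estimated correlation). With the block immediate early genes lost their call without replicate 1 or 3 (camera adjusted p = 0.69 and 0.21) and ATF4 integrated stress response without replicate 1 (camera adjusted p = 0.055). DNA replication passed only with the block (median -0.15; camera adjusted p = 0.038, 0.11 without it, or adjusted p = 0.69 with an estimated correlation and the block).

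Between AKI serum and FBS 42 rows passed in limma, 25 higher and 17 lower (59.5% higher; 50% after quantile normalisation or in the deposited log2 table), and 2431 had an unadjusted p under 0.05. Angptl4 (log2 3.91 ± 0.34, limma adjusted p = 0.0011) and the interferon response gene Usp18 (1.42 ± 0.22, limma adjusted p = 0.032) were among the rows that rose. With the replicate block 1862 passed, 1046 higher and 816 lower. The count was 13, 16 and 4 without FBS replicates 1, 2 and 3 and 13, 23 and 13 without AKI serum replicates 1, 2 and 3. With the block the count was 108, 808 and 28 without replicates 1, 2 and 3.

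Over all 4 media, Arrdc3, Cxcl3 and Slc2a6 were the named genes that passed in the same direction in FBS, sham serum and AKI serum against serum free medium. Arrdc3 differed by 2.15, 1.93 and 1.68 on the log2 scale and Slc2a6 by -2.54, -2.49 and -2.15. Cxcl3 was well above background on 0 of 3 serum free arrays and was at least 2.13-fold higher in FBS. After normexp Cxcl3 differed by 0.10 in FBS and did not pass there (limma adjusted p = 0.90). With 6 unnamed probes, all lower, they made 9 shared rows, 2 higher and 7 lower. With the replicate block 866 were shared (484 higher and 382 lower). Simulated unchanged groups against the same serum free arrays shared 0, and independent lists of the same sizes would share 1.3e-04 higher and 5.8e-04 lower rows. The simulated groups held no changed rows, so their overlap of 0 was set in advance. Neither value shows how many rows the common serum free arrays add to the overlap of called rows. Sham serum and AKI serum shared 68 higher and 137 lower rows, where independent lists would share 1.15 and 2.14. Across the rows, which are not independent replicates, the correlation of log2 fold changes was 0.69 for FBS with sham serum, 0.64 for FBS with AKI serum and 0.90 for sham serum with AKI serum, against 0.50 in the simulation. The covariance was 0.186, 0.188 and 0.325, against 0.033, 0.034 and 0.034. With 3 serum free arrays no 2 sets of 2 could be made, so part of the excess may come from the shared controls.

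The F test of limma over the media called 325 rows (3648 at an unadjusted p under 0.05), and 4970 with the replicate block. The count was 62 without serum free replicate 3, and 171, 157 and 124 without FBS replicates 1, 2 and 3. It was 142, 147 and 130 without sham serum replicates 1, 2 and 3, and 87, 97 and 53 without AKI serum replicates 1, 2 and 3. With the block it was 1030, 1364 and 46 without replicates 1, 2 and 3. The count of shared rows, 9 with all arrays, was 236 without serum free replicate 1, 3 without serum free replicate 2, 0, 1 and 2 without FBS replicates 1, 2 and 3, 1, 1 and 3 without sham serum replicates 1, 2 and 3, and 1 and 5 without AKI serum replicates 2 and 3. The 866 with the block became 529, 0 and 0 without replicates 1, 2 and 3. Relative to the values used here, normexp moved the median of all rows by -0.11 in FBS, -0.12 in sham serum and -0.16 in AKI serum against serum free medium.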

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

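The replicate block, the fit on the 2 groups and the array leave-outs were planned, and the block combined with other settings or with a slide left out, and the leave-outs of the shared rows, were chosen after the results were seen. Counts moved by over 1.5 times were as follows. With quantile normalisation sham serum against FBS gave 1 call, and AKI serum against sham serum with the block gave 3 instead of 13. The deposited log2 table also gave 1 call for sham serum against FBS. Median centring gave 4 calls for FBS against serum free medium and 4 shared rows. Normexp gave 141 (sham serum against serum free medium), 455 (AKI serum against serum free medium) and 206 (F test), and with the block 29 (AKI serum against sham serum) and 1167 (sham serum against FBS). Normexp with quantile normalisation gave 213 for the F test. With no filter on dim probes the counts were 1 (FBS against serum free medium), 55 (sham serum), 300 (AKI serum), 21 (AKI serum against FBS), 65 (F test) and 1 (shared). Signal on all 12 arrays gave 1 (AKI serum against sham serum), 18, 146 and 458 (FBS, sham serum and AKI serum against serum free medium), 1 (sham serum against FBS) and 15 (shared). Every probe as its own row gave 6 for FBS against serum free medium. Array weights gave 4 (AKI serum against sham serum), 127 and 1348 (FBS and AKI serum against serum free medium), 282 (AKI serum against FBS), 493 (F test) and 93 (shared). The replicate block gave 13, 1330, 4433, 6206, 629, 1862, 4970 and 866 for AKI serum against sham serum, the 3 sera against serum free medium, sham serum against FBS, AKI serum against FBS, the F test and the shared rows, and with trend and robust 1119 for sham serum against FBS. The fit on the 2 groups alone gave 0 (AKI serum against sham serum), 1, 0 and 97 (FBS, sham serum and AKI serum against serum free medium) and 82 (AKI serum against FBS). Leaving out 1 array gave 2 calls each time for AKI serum against sham serum, and ranges of 0 to 332, 14 to 564 and 133 to 959 for FBS, sham serum and AKI serum against serum free medium, 0 to 2 for sham serum against FBS, 4 to 23 for AKI serum against FBS, 53 to 400 for the F test and 0 to 236 for the shared rows. With the block and 1 slide left out the ranges were 0 to 2, 0 to 838, 32 to 2333, 945 to 3459, 0 to 122, 28 to 808, 46 to 1364 and 0 to 529 in the order used for the block. The direction reversed once: cholesterol synthesis in AKI serum against sham serum had medians of 0.12, -0.14 and -0.18 without replicates 1, 2 and 3, against -0.07 with all. The cause of these moves was not tested. Of the 33 results of named genes that passed, none lost its call with the block. Losses were 4 with quantile normalisation, 7 with normexp, 8 with normexp and quantile normalisation, 4 with the deposited log2 table and 3 with median centring. They were 5 with no filter, 2 with every probe as its own row and 1 each with array weights, with trend and robust and with signal on all 12 arrays. Among the other gene results 30 gained a call with the block and 7 with array weights. In the leave-outs of single arrays gene calls were lost 60 times and gained 7 times. After normexp Cxcl3 differed by 0.10 between FBS and serum free medium and Lect2 by 0.31 between sham serum and FBS. Of 192 list results only 49 had a call to lose. All 49 lost it with the block and an estimated correlation. With an estimated correlation and no block 47 lost it, and NRF2 targets in AKI serum against sham serum and against FBS kept theirs. Of these calls 7 were lost with the block alone, 10 with quantile normalisation and 5 with normexp. Among the other list results 2 gained a call with the block, 1 with quantile normalisation and 13 with normexp. With the block and 1 slide left out 49 list calls were lost and 21 gained in 576 results. The block also changed calls of list members, over all rows or over the list alone, and not all of these are named here. A fit with the slide as a random block was not run. Since slide and replicate number coincide, it would have grouped the arrays as the replicate block did. The values are intensities after background subtraction, so folds of probes near background depend on that correction, as those of Cxcl3 and Lect2 did. No absolute amounts of transcript follow from them.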

Other observations

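The detoxification enzyme families and the tests of slide position and slide differences were chosen after the results were seen. Members were taken by the start of the gene symbol: Akr, Gst, Mgst, Ugt, Aldh, Adh, Cbr, Abcc, Sult, Ephx, Ces, Fmo and part of Cyp. The Cyp pattern took genes such as Cyp11b1, Cyp24a1 and Cyp27a1 and missed the measured Cyp1a1 and Cyp1b1. The set therefore covers detoxification enzymes only in part. Of 96 members so taken, 9 on the NRF2 list and 5 called ones were left out. Of the 82 tested 47 were higher in AKI serum than in sham serum, with a median of 0.11 and medians of 0.04, 0.13 and 0.08 on slides 1, 2 and 3. Aldh1a7 differed by 1.97 ± 0.71 (SE, n = 3 arrays per medium) with 1 sham serum array well above background, and Akr1b1 by 0.79 ± 0.26, with 0.75, 0.87 and 0.76 on the slides; Akr1b1 was the 1 member that passed in limma when adjusted over these families alone, and only with the block. The median was at percentile 99.9 of random lists matched on mean signal (camera p = 0.015 unadjusted, 0.20 with an estimated correlation).

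The growth factor Gdf15 differed by 1.32 ± 0.62 between AKI serum and sham serum and Fosl1, a member of the AP-1 family, was 2.83-fold higher, neither of which passed in limma (adjusted p = 1). The transferrin receptor Tfrc differed by -1.66 ± 0.59 between FBS and serum free medium and by 1.75 ± 0.59 between sham serum and FBS (limma adjusted p = 0.35 and 0.64, or 0.032 and 0.034 with the block).

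The rise of NRF2 targets in AKI serum against sham serum was not explained by a shift that depends on signal, since its median was at percentile 100 of matched random lists. The lowest median of a slide was 0.51; each slide held 1 array of every medium, so this value is no test of a difference between slides. Among 10 splits of the 6 arrays the real one had a median of 0.64 and the highest other 0.31, and 10 splits are too few for a share under 0.05 (1 of 10 reached the real value). Each medium held 1 position on the slide throughout, so an effect of position may contribute and remains open.

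Cholesterol synthesis genes were lower as a list in FBS, sham serum and AKI serum than in serum free medium with the preset correlation, a call lost with an estimated correlation (camera adjusted p = 0.11, 0.18 and 0.16). The highest percentile of the list among matched random lists was 0 over the 3 comparisons. Serum free replicate 3 alone, the array with the smallest share of probes well above background, could not have produced it, since the highest median on slides 1 and 2 was -0.67.

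More rows passed once the replicate number was in the fit. The lowest correlation of deviations between arrays of 1 slide was 0.40, which is the pairing already described and no separate test of its cause. Scan day was not the whole of the difference between slides. Slides 2 and 3, scanned on the same day, differed with an SD over rows of 0.51. The other pairs had 0.56 and 0.59, so the same-day SD was 0.917 of the smaller. A part played by scan day remains open. What differed between the slides, the culture batch or the hybridisation, may not be told apart from these data.

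For counts of rows the real split of each pair of media gave 2 (AKI serum against sham serum), 10, 222 and 777 (FBS, sham serum and AKI serum against serum free medium), 3 (sham serum against FBS) and 42 (AKI serum against FBS), and 1 of 10 splits, the real one, reached this in each, with 0 as the highest other. There are 10 splits of 3 and 3, too few for a share under 0.05. Against splits that part as many pairs of replicates (4 with the real one), the highest other count with the block was 2 for sham serum against serum free medium and 0 in the other comparisons. For counts of lists the real split gave 11, 4, 6, 6, 16 and 6 in the same order, the highest other 11, 13, 10, 10, 11 and 13, and 2, 9, 6, 5, 1 and 8 of 10 splits reached the real count. Over all media 1 of 100 regroupings, the real one, reached 325 rows in the F test (highest other 144), and 1 of 100 reached 9 shared rows (highest other 0). Regrouping within slides with the block, 1 of 100 reached 4970 rows (highest other 1106) and 1 of 100 reached 866 shared rows (highest other 2). For the F test and the shared rows these shares were under 0.05, and no other regrouping drawn reached the real counts. They do not test an effect of slide position, nor how many shared rows come from the common serum free arrays.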
